A study of Homo sapiens with 2 samples.

How the data were processed

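The data are the cytosine reports of 2 reduced representation bisulfite libraries of 293T cells, which form 1 group by their titles and source names. Per the labels' protocols, DNA was digested with MspI, end-repaired, ligated to methylated adapters, selected for MspI fragments of 40 to 120 and 120 to 220 bp, treated with bisulfite in 2 rounds, amplified and sequenced. The protocol mentions genomic DNA as well as small numbers of cells and does not tie either library to an input. The series title mentions molecular identifiers, and the sources used here do not say whether the deposited counts were collapsed by them, so calls may include copies of a molecule.

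The files deposited by the authors hold, for each cytosine of a CpG, the counts of methylated and unmethylated reads, not normalised. Per the submitters' processing notes, CASAVA 1.8, FastQC and Bismark 0.12.1 were used with the hg19 build. Filters on reads, trimming of filled-in ends and duplicate handling are not given in the sources used here. Untrimmed filled-in ends would lower levels at the ends of fragments, and copies of a molecule would make intervals too narrow.

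All values below were computed from these counts with Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The strands of a CpG were summed, and the level was methylated over all calls. Chromosome Y was left out of every analysis, and chromosome M and unplaced contigs were used only where named. Depth was 1691899 calls in replicate 1 and 680185 in replicate 2. CCGG sites were taken from the CGG contexts on both strands in the files, and fragments run from a site to the next. Positions are 1-based and run from the first to the last CpG.

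Before the data were examined the following were fixed: the minimum of 10 reads, the main tests, the alternatives, 15 gene lists and the rule for naming items. That rule named genes by promoter level, or, without an annotation of the build of the files, the 10 runs of at least 5 CpGs with at least 10 reads in both libraries and gaps under 200 bp that differed most. The gene table used here is of another assembly (GRCh38.p14), so no gene was placed on hg19, and methylation by gene feature and promoter methylation of the 15 gene lists were not run. The planned end-fill difference had no value at 10 reads in replicate 2.

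Since only 22 CpGs had 10 reads in both libraries, levels over every covered CpG, the disagreement of calls, fragments in opposite states, megabase bins, captured fragments and ribosomal DNA, by run, window and MspI fragment, were added after the depth was seen. Disagreement is the chance that 2 different calls at a CpG differ, averaged over CpGs, which does not depend on depth. Its 95% intervals come from 1000 resamples of 1 Mb blocks. Per-CpG differences were tested with Fisher's exact test (two-sided, Benjamini-Hochberg, threshold 0.05), which compares these libraries and not conditions. Excess spread is the Pearson chi-square between libraries or strands divided by its degrees of freedom at CpGs with pooled levels of 20 to 80%. CpG density is the number of CpGs in a 200 bp window centred on the CpG. Shares of chromosome M calls and of fragments have exact Clopper-Pearson intervals. A fragment was captured if a CpG inside it, or its own strand at a starting site, had a call. Expected captures were computed within strata of fragment length (steps of 20 bp) and CpG number. The intervals of the capture ratios come from resampling 5 Mb bins.

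On simulated calls drawn independently, Fisher's test called 94.5% of CpGs changed by 60 points, and 4.06% of its calls were unchanged CpGs. The depths were those of CpGs with 10 reads in both libraries on any contig but chromosome Y. Copies of a molecule are not independent, so these shares may not hold for the real calls. In simulation, the disagreement of calls between the libraries was estimated as 19.9% where the truth was 20.0%. A chromosome captured 1.5 times as often as the others was estimated at 1.49. With 2 libraries of 1 group there is no test between groups, and values are given as mean and SD or per library. Alternatives covered the read minimum, over-covered CpGs, CpGs outside the selected fragments, CCGG sites, single cytosines, weighting, the density window, chromosome X, contigs and each library alone.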

Results

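Bisulfite sequencing of a reduced genome (RRBS) was carried out on 293T cells, a human embryonic kidney line that carries the SV40 large T antigen. In this assay the enzyme MspI cuts genomic DNA at CCGG whether or not the site is methylated, short fragments are kept, and bisulfite treatment turns unmethylated cytosines into bases read as thymine, so that the covered CpGs lie mostly in CpG-rich sequence. The series asks how repeated copies of the same molecule distort a methylome made from very little starting DNA. Both libraries analysed here, replicate 1 and replicate 2, belong to a single group, so the comparisons are between the libraries and between parts of the genome. The series title speaks of single cells and the protocol also of bulk genomic DNA, but the labels do not say which input either library had. A library from few cells would hold few copies of each region. Nothing says that the libraries came from separate cultures, so the spread between them may be technical.

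Of 27999103 CpGs on chromosomes 1 to 22 and X of the hg19 build, replicate 1 covered 947979 (3.39%) with 1691899 calls, and replicate 2 covered 510737 (1.82%) with 680185 calls. Most covered cytosines had a single call, 59.3% of them in replicate 1 and 78.7% in replicate 2. Both libraries covered 188241 CpGs, and 22 CpGs had at least 10 calls in both. The values of most regions therefore rest on many CpGs of low depth, and single CpGs could be compared almost only in ribosomal DNA.

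CpG-dense sequence was mostly unmethylated and CpG-poor sequence mostly methylated in both libraries. On autosomes, CpGs with 15 or more CpGs in the surrounding 200 bp had a mean methylation level of 28.1% ± 3.21 (SD, n = 2), against 82.6% ± 1.83 where 1 to 4 CpGs lay in that window, 84.1% ± 1.59 with 5 to 9 and 73.0% ± 2.68 with 10 to 14. Over all chromosomes the difference dense minus sparsest was -52.2 percentage points in replicate 1 and -53.9 in replicate 2, far larger than the difference between the libraries. These levels use every covered CpG, a minimum of 1 call chosen after the depth was seen. With the minimum of 10 calls fixed before the data were examined, the difference dense minus sparsest was -42.1 points ± 0.451 (SD, n = 2). Only 364 CpGs in replicate 1 and 31 in replicate 2 reached that minimum, and the difference uses only the densest and sparsest of them. Dense ones numbered 140 on autosomes and 19 on X in replicate 1, and 21 and 0 in replicate 2. Of the 31 in replicate 2, 18 lay in a single run on chromosome 21 at 9825832 to 9825996, with a mean level of 52.8%. The small SD of this difference therefore does not show close agreement. With at least 5 calls the difference was -55.5 points in replicate 1 and -60.6 in replicate 2.

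**Figure D1:**
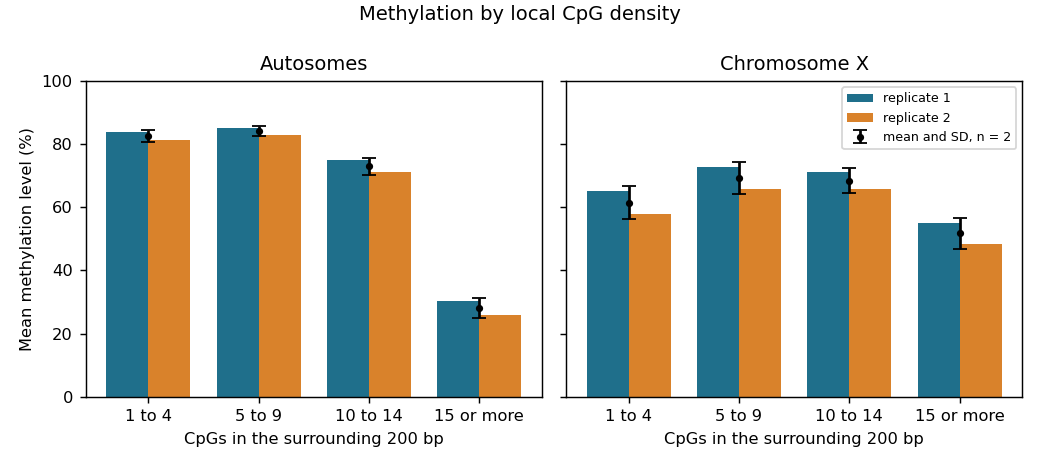
Mean methylation level (%) of every covered CpG by the number of CpGs in the surrounding 200 bp, for autosomes and chromosome X; bars are the libraries, points and error bars the mean and SD of both. Dense autosomal CpGs lie at 30.4% and 25.9%, dense CpGs of chromosome X at 55.1% and 48.3%.

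Chromosome X stood apart from the autosomes in both directions. Its dense CpGs were more methylated than dense autosomal CpGs, by 23.6 points ± 1.60 (SD, n = 2), with mean levels of 51.7% and 28.1%. Its sparsest CpGs were less methylated, with a difference X minus autosomes of -21.2 points ± 3.34 (SD, n = 2) and mean levels of 61.5% and 82.6%. Both differences had the same sign in both libraries and exceeded the spread between them. Every autosome lay below X in the dense class, where the mean of the libraries ran from 19.9% on chromosome 3 to 38.1% on chromosome 19. In megabase bins the lower methylation of CpG-poor sequence on X appeared as well, where the median level over 35 bins of 2 Mb was 70.8% in replicate 1 and 66.1% in replicate 2, against 86.5% and 84.7% over 727 autosomal bins.

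The libraries also disagreed at a higher rate on chromosome X than on any autosome. When 1 call was drawn from each library at a dense CpG covered by both, the calls differed in 35.0% of pairs on X (95% block bootstrap interval 31.0 to 38.9, 2345 CpGs) and in 6.53% on autosomes (6.16 to 6.87, 76436 CpGs), a ratio of 5.37 (4.70 to 6.04). Among autosomes this share ran from 5.19% on chromosome 15 to 8.71% on chromosome 20. X ranked highest of 23 chromosomes, for which the exact one-sided probability under random order is 0.0435, the smallest this ranking allows. CpG-poor sequence, with 1 to 9 CpGs in the window, showed a smaller contrast, with 26.2% of pairs on X differing (23 to 29.8) against 10.3% on chromosome 14 to 13.8% on chromosome 20 among autosomes.

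**Figure D2:**
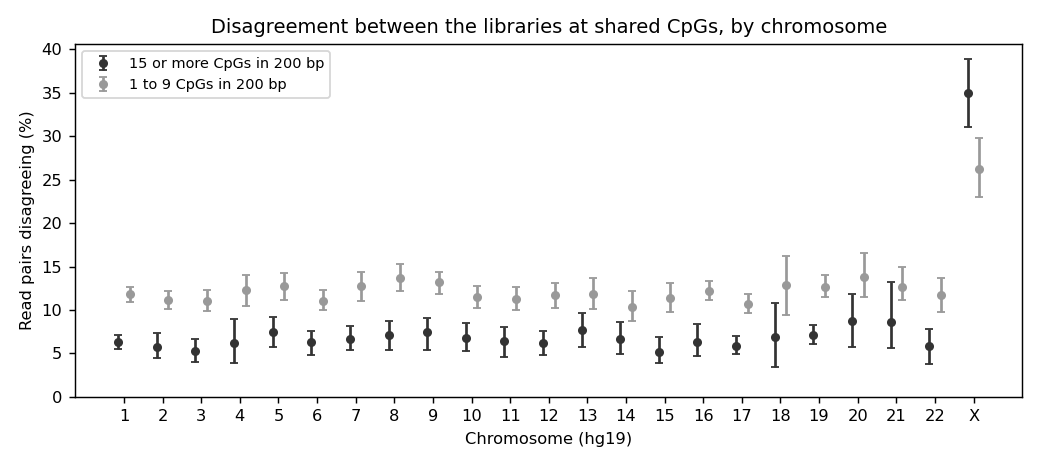
Share of call pairs (%), 1 call from each library, that disagreed at CpGs covered by both, for each chromosome of hg19 and 2 classes of CpG density; points are means over CpGs and bars 95% intervals from resampling 1 Mb blocks. X lies at 35.0% in dense and 26.2% in sparse sequence, and dense sequence of the autosomes lies between 5.19% and 8.71%.

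Some of these differences lay in whole fragments, though the share of the disagreement that such fragments account for was not computed. Of 733 MspI fragments of 40 to 220 bp on X with at least 4 CpGs covered in both libraries, 70 (9.55%, exact 95% interval 7.52 to 11.9) were in opposite states, with levels at least 80 points apart. On autosomes 120 of 19672 were (0.610%, 0.506 to 0.729), so the share was 15.7 times as high on X (two-sided Fisher exact p = 6.67e-52, fragments taken as independent). The X fragments went both ways, 37 being more methylated in replicate 1 and 33 in replicate 2 (two-sided exact binomial p = 0.720). On autosomes 73 were more methylated in replicate 1 and 47 in replicate 2 (exact p = 0.0221).

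The fragments with the most shared CpGs, picked after their values were seen, show what such a difference rests on. On X, the fragment at positions 18372765 to 18372865 was unmethylated at all 18 shared CpGs in replicate 1 and methylated at all of them in replicate 2, from 18 and 19 calls, which is about 1 read in each library. The fragment at 17674308 to 17674450 on X had 100% in replicate 1 and 12.5% in replicate 2 over 16 CpGs, from 51 and 34 calls, more than 1 read in either. The X fragment at 53710876 to 53710982 was likewise at 0% and 100% over 16 CpGs, from 16 calls in each. In the other direction, 53111602 to 53111707 on X was at 92.3% in replicate 1 and 0% in replicate 2 over 13 CpGs. The autosomal fragment with the most shared CpGs lay on chromosome 16 at 67212347 to 67212495, with 100% and 0% over 18 CpGs from 18 and 36 calls. On chromosome 2, the fragment at 219757840 to 219758001 had 94.1% and 0% over 17 CpGs from 53 and 18 calls, and on chromosome 1 the fragment at 29448507 to 29448585 had 96.4% and 0% over 14 CpGs from 28 and 14 calls. No gene annotation of this build was used here, so these regions are given by position only.

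Calls from the same strand of the same CpG within a library were more alike than calls from opposite strands or from different libraries. On dense autosomal CpGs, 2 calls of the same strand differed at 2.00% (95% block bootstrap interval 1.86 to 2.15) in replicate 1 and 2.28% (1.98 to 2.64) in replicate 2. Calls of opposite strands differed at 5.88% (5.50 to 6.30) and 5.44% (4.81 to 6.14). The share was 6.29% (5.89 to 6.71) for same-strand calls from different libraries. For opposite-strand calls from different libraries it was 6.81% (6.36 to 7.27), above the intervals of opposite strands within either library. The kinds of pair rest on different sets of CpGs, so this difference does not settle how few copies each library sampled. On dense X CpGs all of these shares were higher, with 9.34% (7.0 to 11.8) and 21.9% (15.9 to 29.1) for the same strand. They were 31.7% (25.1 to 38.1) and 36.2% (27.2 to 46.7) for opposite strands, and 33.7% (29.3 to 38.1) for the same strand of different libraries. Opposite strands of different libraries differed at 37.8% (32.6 to 42.9) on X, where the intervals overlapped those of opposite strands within either library. These intervals resample blocks of the genome and do not cover the spread between libraries. Calls are not independent molecules, so the exact intervals given for shares of fragments and of chromosome M calls cover counting error only.

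**Figure D3:**
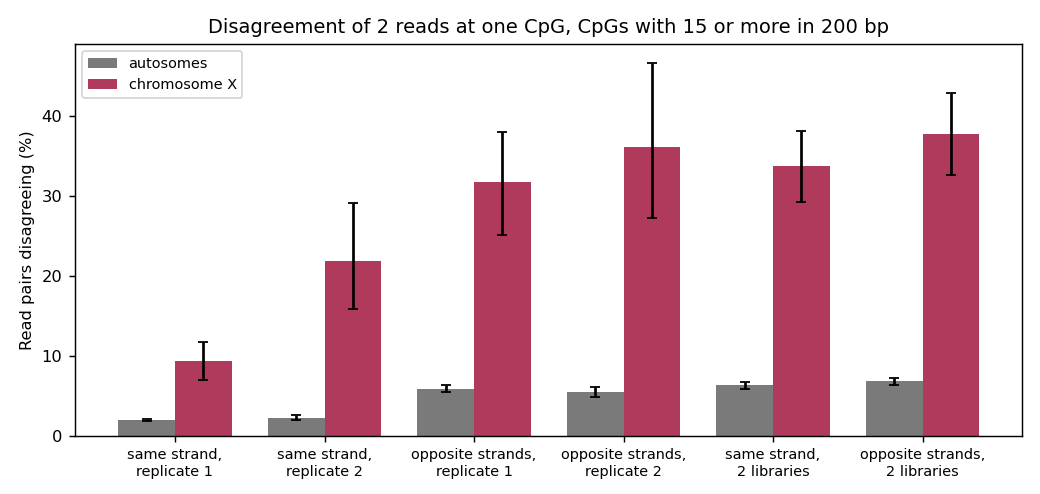
Share of call pairs (%) that disagreed at a CpG with 15 or more CpGs in 200 bp, by the origin of the calls, for autosomes (grey) and chromosome X (red); bars are means over CpGs and error bars 95% intervals from resampling 1 Mb blocks. Autosomal same-strand pairs lie at 2.00% and 2.28%, opposite-strand pairs at 5.88% and 5.44%, and X exceeds the autosomes for every kind of pair.

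The mean over every covered CpG was 63.2% in replicate 1 and 57.3% in replicate 2, or 60.2% ± 4.19 (SD, n = 2). At the 188241 CpGs that both libraries covered, the levels were 58.3% and 58.0%, a difference of 0.30 points (95% block bootstrap interval 0.123 to 0.505) that turned to -0.0174 (-0.469 to 0.436) at CpGs with at least 2 calls in both. Nearly all of the gap lay in CpGs covered by a single library, with 64.4% and 56.8%. Giving replicate 2 the density classes in the shares of replicate 1 raised it from 57.3% to 59.6%. With at least 10 calls the mean was 69.9% ± 0.166 (SD, n = 2), over only 364 CpGs in replicate 1 and 31 in replicate 2. This small SD does not show close agreement, since with at least 5 calls the levels were 67.0% and 55.7%.

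Across the 22 CpGs with at least 10 calls in both libraries, levels correlated with Pearson r = 0.927 and Spearman rho = 0.917, and read sampling alone would give r = 0.838. CpGs are not independent replicates, and 18 of these lie within 200 bp of one another in the run on chromosome 21 at 9825832 to 9825996, where the levels were 56.1% and 52.8%. No CpG of the 22 passed Fisher's exact test at an adjusted p of 0.05 (Benjamini-Hochberg), and 0 had an unadjusted p under 0.05. With at least 5 calls r was 0.823 over 185 CpGs, below the 0.885 of read sampling alone. Over 188241 shared CpGs r was 0.813, against 0.913 from read sampling. That expectation draws both libraries from the pooled level of the same calls, which at few calls raises it by construction. At 1 or 2 calls the gap therefore says nothing about spread beyond read sampling, and at 5 calls it is affected to an unmeasured extent. Of the 188241 CpGs 0 passed, with 110 under an unadjusted 0.05, but with 1 or 2 calls in a library Fisher's test cannot reach a small p. The chi-square between the libraries, relative to read sampling, was 0.367 over 18 CpGs and 1.36 (0.936 to 1.78) over 80 CpGs with at least 5 calls, and between the strands of a CpG in replicate 1 it was 2.13 over only 3. Of dense CpGs with at least 10 calls in replicate 1, 68.4% of 19 on X and 37.1% of 140 on autosomes had levels of 20 to 80%, a ratio of 1.84, which turned to 0.706 over 17 X CpGs with at least 20 calls. Replicate 2 had 0 such CpGs on X. With at least 5 calls the ratio was 5.11 in replicate 1 and 4.83 in replicate 2.

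Ribosomal DNA held nearly all of the nuclear CpGs with at least 10 calls in both libraries. The unplaced contig chrUn_gl000220, which carries copies of the ribosomal RNA gene unit in this build, held 36292 calls in replicate 1 and 17233 in replicate 2, and 427 of its CpGs between 118138 and 145362 had at least 10 calls in both. Their mean level was 63.9% ± 0.899 (SD, n = 2), with r = 0.878 and rho = 0.893 across CpGs, against r = 0.940 from read sampling. Without an annotation of this build, it was not determined whether these CpGs lie in the ribosomal RNA genes or between them. In windows of 2500 bp the level was 38.6% and 42.9% from 117500 to 119999, 89.2% and 82.8% from 122500 to 124999, and 86.5% and 82.7% from 142500 to 144999. Between the latter windows it fell to 37.9% and 37.1% from 132500 to 134999. A run of 19 CpGs at 134742 to 135021, picked after its values were seen, was at 17.3% and 16.9%, from 1134 and 763 calls, while the run of 31 CpGs at 143188 to 143881 was at 85.3% and 80.3%.

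**Figure D4:**
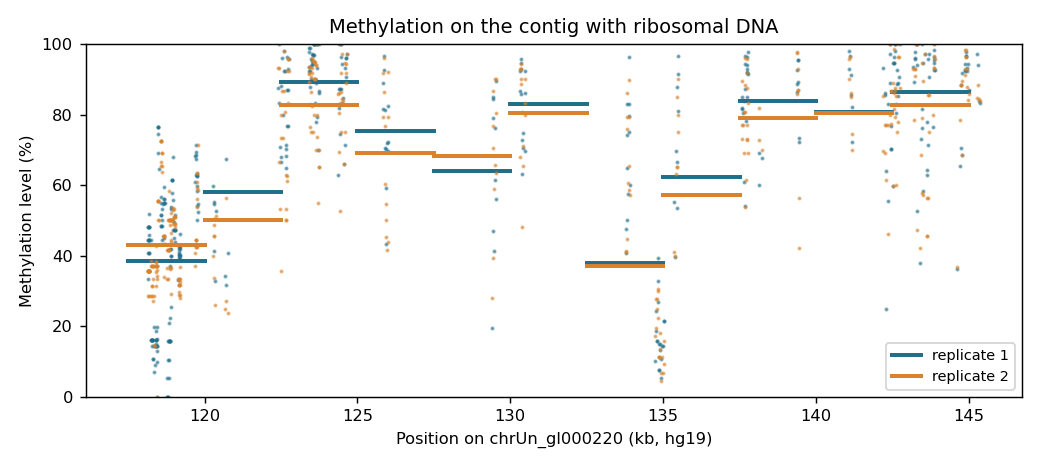
Methylation level (%) along the contig with ribosomal DNA (position in kb, hg19); points are CpGs with at least 10 calls in both libraries and horizontal lines the mean over windows of 2500 bp with at least 5 such CpGs. Levels rise and fall along the contig, with 38.6% and 42.9% in the first window, 37.9% and 37.1% from 132500 to 134999, and 86.5% and 82.7% in the last.

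Only 23 runs of at least 5 well-covered CpGs existed, 18 on this contig, 4 on chromosome M and 1 on chromosome 21. The 10 runs that differed most between the libraries all lay on this contig, which held most of the runs. The 4 on chromosome M were almost unmethylated in both libraries and could hardly differ. The largest difference in the mean of a run was 10.05 points, at 119696 to 119783, with 61.6% in replicate 1 and 51.6% in replicate 2 over 16 CpGs. It was followed by the run at 122415 to 122751, with 83.0% and 74.8%, the run at 120287 to 120375, with 49.6% and 41.5%, and the run at 123404 to 123743, with 93.0% and 86.2%. The runs at 137567 to 137789, 125831 to 126018, 139371 to 139456 and 143188 to 143881 were higher in replicate 1 by 6.70, 6.41, 5.80 and 4.99 points. The run at 118138 to 119210, the longest with 126 CpGs, was lower in replicate 1, with a mean of 35.7% against 41.8%, as was that at 129405 to 129537, with 63.9% against 68.2%. The mean of the longest run hid larger differences of both signs between its MspI fragments, a division chosen after the values were seen. At 118777 to 118874 the level was 10.9% in replicate 1 and 44.0% in replicate 2, lower in replicate 1 at all 17 CpGs, from 349 and 221 calls. At 118253 to 118452 it was 15.2% and 32.7% over 31 CpGs, and at 118472 to 118507 it was 72.9% and 53.7%, higher in replicate 1 at all 6. CpGs of a fragment share reads and are not independent. Of the 427 CpGs, 1 passed Fisher's exact test after Benjamini-Hochberg adjustment and 76 had an unadjusted p under 0.05. This CpG, at 125969 to 125970, had 115 of 160 calls methylated in replicate 1 and 22 of 53 in replicate 2 (Fisher's exact test, adjusted p = 0.0491), and it did not pass once the test was scaled by the excess spread. The spread between the libraries was 2.40 times that of read sampling over 238 CpGs of intermediate level. In simulated calls, counting every read 2 times gave 2.03, so this ratio does not separate a difference between the libraries from copies of molecules.

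In some autosomal bins of 2 Mb the covered CpG-poor sequence was poorly methylated in both libraries. Of 727 bins of 2 Mb with at least 100 calls in each library, 15 were under 60% in both. The bin from 10000000 to 11999999 on chromosome 21 had 31.3% in replicate 1 and 30.7% in replicate 2, that from 2000000 to 3999999 on chromosome 5 had 38.5% and 31.2%, and that from 126000000 to 127999999 on chromosome 12 had 36.3% and 41.3%. The lowest mean, on chromosome 16 from 6000000 to 7999999, rested on levels as far apart as 40.5% and 15.9%, from 190 and 126 calls. The bins named on chromosomes 21 and 12 held 195 and 157 calls in replicate 1, and 137 and 126 in replicate 2. So few calls cover a small part of a bin, and a low level need not extend along it. The highest bin was on chromosome 14 from 58000000 to 59999999, with 95.7% and 95.1%. Across the bins the levels of the libraries correlated with r = 0.808 and rho = 0.557, and r was 0.796 without the 2 bins farthest from the median.

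The share of MspI fragments that each library captured also differed by chromosome. Replicate 1 captured 172901 of 645356 fragments of 40 to 220 bp (26.8%) and replicate 2 captured 93015 (14.4%), with 41904 in both, so that most fragments of each library were absent from the other and they were kept as 2 samples. The overlap was 1.53 times the number expected had they been captured independently given length and CpG number. Relative to the genome-wide shares, replicate 1 held more of chromosome 13 (log2 ratio 0.35, 95% bootstrap interval 0.23 to 0.54), chromosome 3 (0.32, 0.25 to 0.38), chromosome 19 (0.29, 0.23 to 0.35) and chromosome 15 (0.21, 0.12 to 0.28). It held less of chromosome 8 (log2 ratio -0.22, -0.28 to -0.16), chromosome 21 (-0.17, -0.29 to -0.08), chromosome 2 (-0.17, -0.22 to -0.10) and chromosome 6 (-0.16, -0.23 to -0.08), and of X the log2 ratio was -0.15 (-0.23 to -0.07). In all, 6 chromosomes had intervals above 0 and 10 below.

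**Figure D5:**
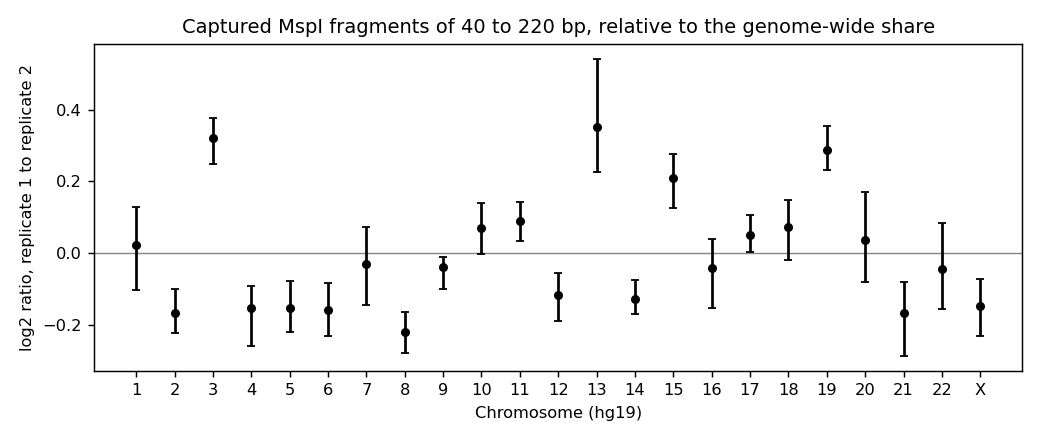
Log2 ratio of captured MspI fragments of 40 to 220 bp, replicate 1 to replicate 2, for each chromosome of hg19 after standardising for fragment length and CpG number; points are chromosomes and bars 95% intervals from resampling 5 Mb bins. Chromosomes 13, 3, 19 and 15 lie at 0.35, 0.32, 0.29 and 0.21.

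Background calls were low. On chromosome M, used as a largely unmethylated internal reference, 66 of 7272 calls were methylated in replicate 1 (0.908%, exact 95% interval 0.703 to 1.15) and 36 of 3373 in replicate 2 (1.07%, 0.749 to 1.47), a mean of 0.987% ± 0.113 (SD, n = 2). Cytosines of CCGG sites that only a fragment ending there could cover had lower levels than those that only a fragment starting there could cover. The levels were 64.1% and 75.0% in replicate 1, over 9603 and 127749 cytosines. In replicate 2 they were 68.3% and 69.8%, over 4550 and 63830 cytosines. The difference was negative in both libraries, at -11.0 and -1.49 points. Its mean of -6.23 points ± 6.71 (SD, n = 2) did not exceed the spread between the libraries, which differed in its size. The 2 sets of cytosines are different sites and were not matched. With at least 5 calls the mean difference was -1.06 points, but over only 85 cytosines at fragment ends in replicate 1 and 4 in replicate 2.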

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

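The tests in this part were chosen after the patterns were seen, and only those on over-covered CpGs, on the choice of CpGs, on end-filled sites and on fragment length were set before their own results were seen. Calls on other unplaced and unlocalized contigs, which the report's main values do not use and only an alternative setting includes, stood above the 3 calls that a count of 0 allows, with 4627 calls in replicate 1 and 2472 in replicate 2 and mean levels of 62.2% and 56.0%. The contig with the most of these calls, chrUn_gl000225, held 1441 and 871, at 57.9% and 49.9%.

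Dense CpGs of chromosome X disagreed between the libraries more often than dense autosomal CpGs. A shift of the whole chromosome in a library is argued against by the fragments in opposite states, of which 52.9% (40.6 to 64.9) were methylated in replicate 1. A candidate explanation is that the cells hold copies of X in 2 methylation states, as X inactivation gives, and that each library sampled few copies of a region. On the 2 states, opposite strands within a library disagreed at dense X CpGs 5.39 times (4.32 to 6.50) as often as on autosomes in replicate 1. In replicate 2 the ratio was 6.65 (4.83 to 8.83). These ratios do not bear on how few copies were sampled, which was not tested. Collapsed repeats stay open: the ratio of X to autosomes was 5.34 (4.71 to 6.03) without CpGs of more than 4 reads on a strand, but this left out only 72 of 2345 dense X CpGs and decides nothing. Differences between cells that are not tied to the copy stay open too, and the labels do not say how many cells either library came from.

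Calls of the same strand within a library disagreed less often than calls of opposite strands. Different CpGs behind the comparisons are argued against by CpGs that have both kinds of pair, where the higher ratio of the libraries was 0.471 (0.410 to 0.534). End-filled sites are argued against by the ratio of 0.479 (0.410 to 0.543) without CpGs of CCGG sites. Copies of a molecule counted more than once may account for the pattern, since same-strand calls of a library disagreed 0.441 times (0.401 to 0.481) as often as same-strand calls of different libraries at the same CpGs, in the library with the higher ratio. At dense X CpGs alone this ratio was less certain, at 0.386 (0.253 to 0.523) in replicate 1 and 0.588 (0.350 to 0.885) in replicate 2. Reads of the same chromosome copy in few cells stay open, since these counts do not separate them from copies, and no biological explanation was tested.

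The ratio of captured fragments between the libraries differed between chromosomes. Fragment length and CpG number do not account for it, since standardising for both left 1.004 times the SD of the log2 ratios, and neither does random scatter of 5 Mb bins over chromosomes (permutation p = 1e-05, the smallest that 100000 permutations can give). Different numbers of copies of long segments may account for it: the log2 ratios of the first and the second part of each of 23 chromosomes correlated with r = 0.705 (0.413 to 0.866, permutation p = 0.0001) and rho = 0.635 (permutation p = 0.00147), and with r = 0.569 (permutation p = 0.00707) without chromosomes 3 and 13. Chromosome 1 goes against whole-chromosome agreement, with a log2 ratio of 0.38 up to 30 Mb and -0.15 from there on, a border picked from the bins. Uneven loss of DNA along chromosomes stays open, since it would give the same pattern, and the labels do not say whether the libraries share a culture.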

How the results depend on the processing

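Settings with at least 1 read, with contigs, and of results added after the depth was seen were chosen after seeing the data. Of 94 alternatives, 63 were rated as unchanged, 30 as moved and 1 as turned in sign. Unchanged meant under 1 SD of the libraries from the main value, within its interval or, for counts, equal or close. Each library alone always lies within 1 SD of the mean of 2, so those settings could not be rated as moved. The count of CpGs differing on the chromosomes was 0 in every setting. The 63 therefore overstate how stable the values were. The mean level with at least 10 reads, 69.9%, was 61.4% with 5, 87.7% with 20 (75.4% over 40 CpGs and 100% at 1 CpG) and 60.2% with 1, 68.8% in selected fragments, 68.9% without CCGG, 71.8% by cytosine, 65.5% with contigs and 70.6% weighted by depth. The difference dense minus sparsest, -42.1 points, was -58.1 with 5 reads, -53.0 with 1, -44.3 without CCGG, -31.9 by cytosine and -44.4 in a 400 bp window. Over every covered CpG, at -53.0, it was -55.1 with 2 reads, -54.3 in selected fragments and -54.5 without X. The correlation was 0.823 with 5 reads and 0.813 with 1. The excess spread was 1.36 with 5 reads, 0.642 by cytosine and 0.614 at pooled levels of 5 to 95%. The share of intermediate dense CpGs on X against autosomes was 5.11 times with 5 reads and 0.706 times with 20, in replicate 1. Disagreement between the libraries, 10.1%, was 10.7% with 2 reads, 9.57% without CCGG and 9.40% without X. Disagreement of opposite strands, 8.72%, was 8.31% without CCGG and 8.10% without X. The ratio of X to autosomes was 6.31 with 2 reads. The difference of 0.30 points at shared CpGs turned to -0.0174 with 2 reads, where its interval holds 0 (-0.469 to 0.436). The cause of these shifts was not tested beyond the CpGs each setting keeps. The single ribosomal CpG passing the test was not called, at 0, once scaled by the excess spread. Each library alone gave 69.8 to 70.1%, -42.4 to -41.7 points, 57.3 to 63.2%, -53.9 to -52.2 points, 8.49 to 8.95% and 2.84 to 3.23% (opposite and same strands), 0.908 to 1.07% (chromosome M) and -11.0 to -1.49 points (end fill, -1.06 with 5 reads), in that order of results. No value could be had where no CpG or too few were left: at 10 reads without the most covered CpGs, and with 20 reads for density, correlation and both excess spreads, and in selected fragments for density, and replicate 2 for X. Methylation by gene feature, the gene lists and the planned end-fill difference were not run. Depth limits single-CpG statements almost entirely to ribosomal DNA.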

Other observations

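Chromosomes 18 and 21 stood apart in both libraries in how often their fragments were caught, given length and CpG number. Chromosome 21 was captured at 1.25 times the expected number in replicate 1 and 1.41 times in replicate 2, and chromosome 18 at 0.614 and 0.583 times. Over 23 chromosomes these values correlated with r = 0.718 (permutation p = 0.00014) and rho = 0.553 (permutation p = 0.00701), and with r = 0.430 (permutation p = 0.0540) without the 2 chromosomes farthest from the median, so the relation rests largely on those.

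Fragments of intermediate or mixed state were more frequent on X. Of the X fragments with at least 4 shared CpGs, 14.6% were at 20% or less in both libraries and 33.3% at 80% or more in both, against 34.6% and 47.3% of autosomal fragments. Neither of these nor in opposite states were 42.6% of X fragments and 17.5% of autosomal fragments.

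Further autosomal fragments in opposite states were at 109674554 to 109674629 on chromosome 10, with 100% in replicate 1 and 0% in replicate 2 over 13 CpGs, and at 150254366 to 150254536 on chromosome 1, with 0% and 92.3% over 13 CpGs.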
